A study of Caenorhabditis elegans with 2 samples.

How the data were processed

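Whole L3 larvae of Caenorhabditis elegans were profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels, the strain OP75 carries an unc-119 mutation and a transgene that makes ELT-3 with GFP and FLAG tags at its C terminus, the animals were of mixed sex, and the 2 samples are biological replicates 1 and 2 of a single group. Fragmentation was by sonication, per the labels. The labels name a possible control experiment, whose files were not used here, and each replicate list was derived from the alignment of that replicate together with a further file, per the descriptions deposited beside the lists. The identity of that further file, the aligner, the peak caller and the threshold on the irreproducible discovery rate (IDR) are not given in the sources used here.

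The deposited lists hold 1 region per line with a signal value that the authors' peak caller gave each region, and this signal is the only measurement used. Its scale is not given in the sources used here, so it served to rank, filter and describe regions within a list. A further score column of the deposited lists is not explained there and was not used. For each build, ce10 and ce11, there is 1 list per replicate, 1 list called on both replicates pooled and 1 IDR list, which per the deposited descriptions was derived from the pooled and both replicate lists. In ce11 the replicate and pooled lists hold 30000 regions each, peaks and background together, and the IDR list holds 774, against 791 in ce10. Region width is fixed within a list, at 344 bases in replicate 1, 336 in replicate 2 and 340 in the pooled and IDR lists of ce11, with the summit at the centre. All 774 IDR peaks are the 774 highest regions of the pooled list by signal. No read counts are in the lists, so sequencing depth is unknown, and precision is set by the number of peaks. Intervals on shares are 95% exact Clopper-Pearson intervals and cover counting error only. For gene lists with 0 members that had an IDR peak at the promoter, the limit of 3 counts of the total is given beside the exact one. A peak was given the signal of a replicate where a summit of that replicate's list lay inside it, a narrower rule than overlap.

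Positions are 1-based on ce11, which has the coordinates of the WBcel235 assembly used for sequence. Genes came from Ensembl release 115, with 19973 protein-coding genes on the nuclear chromosomes. The promoter window ran from 1000 bases upstream to 200 bases downstream of any annotated start of a protein-coding transcript. Many worm transcripts are trans-spliced, so an annotated start can lie downstream of where transcription begins. The ce10 lists were used for counts, chromosome shares and replicate overlap, and no coordinate was converted between builds.

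Replicates were compared by the share of the 774 strongest regions of each list that overlap at least 1 base of the 774 strongest of the other, with chance taken from a permutation by 10000 circular shifts along each chromosome. The same shifts gave chance values for promoter and gene feature shares, two-sided, and the smallest p they can give is 2e-04. The sequence WGATAR (W is A or T, R is A or G), which GATA factors recognise, was sought on both strands in windows of 201 bases at the summit and in windows centred 500 bases to either side, with a two-sided Fisher exact test. Each sequence of 6 bases, counted with its reverse complement, was tested in the same windows with Benjamini-Hochberg adjustment. These tests treated all windows as independent and did not use the pairing of each summit with its own flanks. Each of 19 gene lists was tested for genes with an IDR summit in the promoter window against all other protein-coding genes by a two-sided Fisher exact test, adjusted over the lists at 0.05. Density on X was tested with an exact binomial test on chromosome length, and signal with and without WGATAR by a two-sided permutation test of medians on the log2 scale with 100000 resamples. Regions around elt-3 were counted within 20 kb of the gene midpoint and ranked among windows of 40 kb tiled over X. Peaks and genes are not replicates, so these p-values describe the lists and not variation between animals.

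Tests, lists of genes, most alternatives and the rule for named genes were fixed before the data were examined. The rule names elt-3 and unc-119, the gene whose start is nearest where one of the 25 strongest IDR peaks lies in its promoter window, and up to 4 bound members per list with the strongest promoter peak. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were the 387 strongest IDR peaks, the 774 strongest regions of either replicate alone, promoter windows starting 500 or 2000 bases upstream, assignment to the nearest start within 5000 bases, other motif windows, controls and tests, and other overlap rules.

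The procedures were tested on simulated data. With 19973 genes and binding made 8 times as frequent in the ribosomal protein list, the gene list test recovered that list in 97% of 100 runs, and in 49% at 4 times. For the list of antimicrobial peptides the shares were 50% and 13%. With no list changed, it made 0.02 and 0.01 false calls per run in the 2 sets of runs. The simulation drew each gene as bound independently of the others. In the data a single peak can reach several genes, so these rates do not cover that dependence. In a single run, a planted GATA sequence in a fraction of 0.1 of windows was recovered among all sequences of 6 bases. That run made 1 false call, as did a run with nothing planted, and a run at 0.3 made 7. Calls counted as false can include sequences that overlap the planted one in part. All these windows were drawn away from real summits, so the counts do not cover the difference in base composition between summits and flanks. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.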

Results

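ELT-3 is a GATA-type zinc finger transcription factor known from the epidermis (hypodermis) of the worm. Its tagged form was profiled by ChIP-seq in whole L3 larvae, with 2 biological replicates of 1 group and no second condition, so the comparisons possible are between replicates, between bound and other positions of the genome, and between gene groups. The IDR list of 774 peaks in ce11 had signal values from 29.5 to 133.1 with a median of 36.8. No read counts were at hand, so depth is unknown.

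The strongest binding lay both at promoters and far from them. The highest peak, at IV 13919233 to 13919572, had a signal of 133.1 and lay outside protein-coding genes, 6374 bases from the nearest coding start, and it held 5 WGATAR sequences. Of the 25 strongest peaks, 9 lay in a promoter window, 17 outside protein-coding genes and 8 in introns, and 20 held WGATAR. The strongest promoter peak was that of *oatr-1*, which encodes an ornithine aminotransferase, at III 6396522 to 6396861, 510 bases upstream of the start, with a signal of 99.6. It was followed by peaks upstream of C33D9.3 (97.6, IV 8793189 to 8793528) and F45D3.4 (90.7, V 12553387 to 12553726). A peak at III 15254 to 15593 (87) lay between H10E21.1 and *nhr-80*, a nuclear hormone receptor of fatty acid metabolism, within the promoter window of both. *iff-2*, which encodes a translation factor of the eIF5A family, shared its peak (86.5, II 8561309 to 8561648) with F54C9.14, and this peak held no WGATAR. The remaining ones were at *gly-6*, a glycosyltransferase gene with the peak in an intron (81.7, III 4328650 to 4328989), *elt-3* itself (80.4), the histone gene *his-37* (79.6, V 9546873 to 9547212) and *tasp-1* with K01G5.10 (79.6, III 10759082 to 10759421). The peak of *tasp-1* also lacked WGATAR.

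Among strong peaks chosen after their values were seen, *mec-17*, a tubulin acetyltransferase gene of the touch neurons, had an intronic peak with a signal of 81.1, and *egl-27* an intronic one at 75.3. Upstream of the antimicrobial peptide gene *nlp-24* a peak lay at V 11614781 to 11615120, 1425 bases before the start and so outside the promoter window, with a signal of 76.5 and 3 WGATAR sequences.

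The replicates shared many strong sites but differed in which sites were strong. Of the 774 strongest regions of replicate 1, 350 (45.2%) overlapped the 774 strongest of replicate 2, and 353 (45.6%) the reverse. Shifted lists shared 0.548% on average and 10.1% at most (permutation by circular shifts, p = 2e-04, the smallest possible). Of the IDR peaks, 598 (77.3%, interval 74.1 to 80.2) overlapped the strongest regions of replicate 1 and 482 (62.3%, 58.8 to 65.7) those of replicate 2, 344 (44.4%) overlapped both, and 38 (4.91%) neither. At the *oatr-1* peak the signal was 59.3 in replicate 1 and 39.1 in replicate 2, at *his-37* 44.9 and 29.6, and at *tasp-1* 37.2 and 40.2. The lists need not share a scale (their medians were 8.18 and 5.91), so these pairs show signal in both replicates and not which had more. Over the 757 IDR peaks that contained a summit of both replicate lists, Spearman's rho of the signal was 0.0519 and Pearson's r on the log2 scale 0.128, across peaks, which are not independent replicates. These peaks had been selected by pooled signal, which narrows their range. Over the 10121 pooled regions with a summit of both replicates, rho was 0.332.

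**Figure D1:**
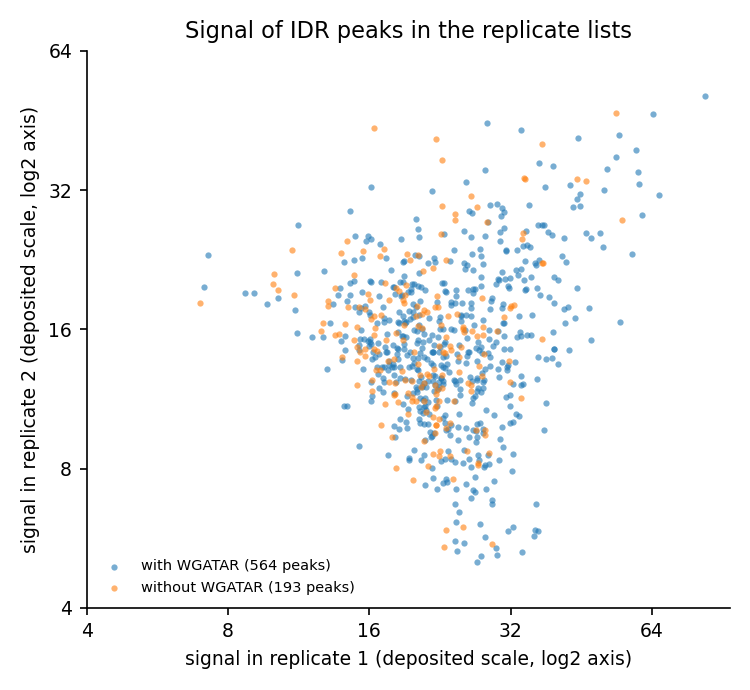
Each point is an IDR peak, with its signal in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on the deposited scale with log2 axes, coloured by the presence of WGATAR within 100 bases of the summit. The 757 peaks that contain a summit of both lists form a broad cloud (Spearman's rho 0.0519).

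Strong sites found in a single replicate carried the GATA sequence less often in replicate 2. Of the 424 strong regions of replicate 1 with no counterpart among those of replicate 2, 295 (69.6%, interval 65.0 to 73.9) held WGATAR, against 249 of 421 (59.1%, 54.3 to 63.9) of those of replicate 2 alone (Fisher exact test, odds ratio 1.58, adjusted p = 0.00795 over 5 measures). Shared regions held it in 77.4% (replicate 1) and 77.9% (replicate 2). Body-shape collagen genes numbered 4 at regions of replicate 1 alone and 0 at those of replicate 2 alone (adjusted p = 0.145, Fisher exact test), and ribosomal protein genes 2 and 7 (adjusted p = 0.293). No sequence of 6 bases differed between these sets after adjustment of Fisher tests, with 148 at an unadjusted p under 0.05. This comparison was chosen after the data were seen.

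ELT-3 sites were concentrated upstream of genes and rare in coding sequence. Of the 774 IDR summits, 343 (44.3%, interval 40.8 to 47.9) lay in the promoter window of a protein-coding gene, against 25.6% on average and 32.2% at most after shifting (permutation p = 2e-04, the smallest possible). They reached the promoter windows of 388 genes (1.94% of coding genes). The median distance to the nearest coding start was 1018.5 bases, and 727 peaks (93.9%) lay within 5000 bases. Coding sequence held 18 summits (2.33%, against 24% after shifting) and 5′ UTRs held 35 (4.52%, against 1.77%), each with an adjusted permutation p of 3.33e-04. Introns held 215 (27.8% against 33.7%, adjusted permutation p = 0.00225), 3′ UTRs 16 (2.07% against 3.38%, adjusted p = 0.0496), and 490 summits (63.3% against 37.1%) were outside protein-coding genes. Among the 29226 pooled regions below the IDR threshold, 30.4% lay in promoter windows.

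The sites carried the GATA sequence. WGATAR lay within 100 bases of the summit in 575 of 774 IDR peaks (74.3%, interval 71.1 to 77.3) and in 601 of 1548 flanking windows (38.8%; Fisher exact test, odds ratio 4.55, p = 4.25e-60). The narrower form TGATAA, a spelling of WGATAR and so part of the same count, occurred at 58.1% of summits and in 20% of flanks. In 4 parts of the list from the strongest to the weakest, WGATAR was present in 82.4%, 78.4%, 69.9% and 66.5% of peaks. Promoter peaks (72.0%) and other peaks (76.1%) were not distinguishable (Fisher exact test, p = 0.214). Of 360 orders of the letters of WGATAR, this one ranked 1 by odds ratio, and the highest odds ratio of an order that cannot spell GATA was 2.79.

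**Figure D2:**
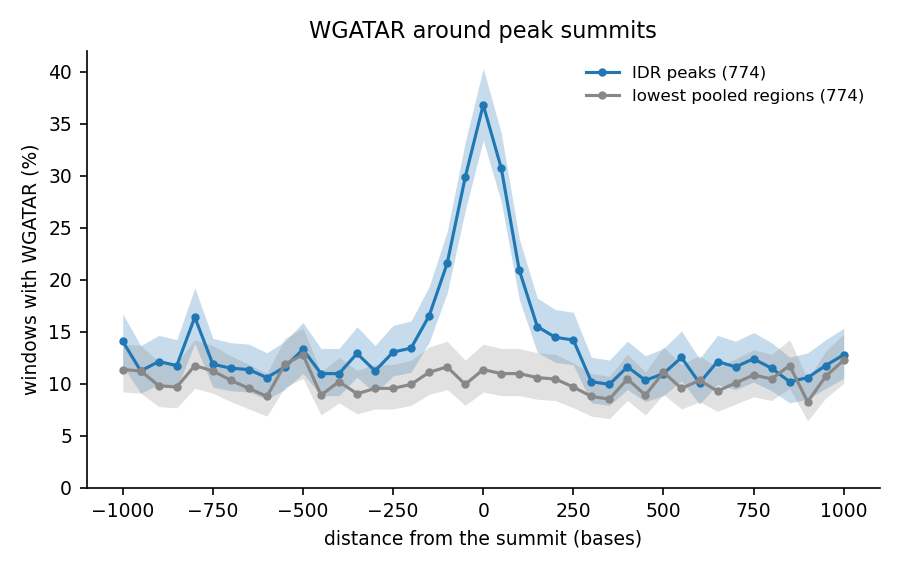
The share of windows of 51 bases that hold WGATAR (y axis, percent) is plotted against distance from the summit (x axis, bases) for the 774 IDR peaks and for the 774 lowest regions of the pooled list, with shaded 95% exact intervals. The IDR peaks rise to 36.8% at the summit, while the lowest regions stay near their flanks.

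A search without a chosen motif returned the GATA sequence first, with a GA repeat among the other enriched sequences. Of all sequences of 6 bases, 460 were more frequent at summits than in flanks and 323 less frequent (Fisher exact tests, Benjamini-Hochberg adjusted p under 0.05). GATAAG (reverse complement CTTATC) led, at 43.7% of summits and 8.85% of flanks (Fisher exact test, odds ratio 7.98, adjusted p = 3.15e-78). Among the enriched sequences were 32 of the 48 that contain GATA on either strand. All 16 in a class of GA repeats, which was not fixed in advance, were enriched as well. GAGAGA was present in 34.4% of summit windows and 11.8% of flanks (Fisher exact test, odds ratio 3.91, adjusted p = 4.33e-34). GAGACG, not itself a GA repeat, was present in 18.2% and 4.65%. Sequences that overlap it or each other were enriched too, AGACGC at 13.7% against 3.49% and ACGCAG at 12.8% against 3.10%. Of the 36 sequences made of A and T alone, a class chosen after the data were seen, 34 were depleted and 0 enriched, with AAAATT at 31.9% against 62.7%. TTTCAG was depleted as well, at 10.3% against 31.2%. Base composition differed in the same direction, with 39.9% G and C in summit windows against 35.1% in flanks.

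GAGAGA was present at 33.7% of summits without WGATAR (interval 27.1 to 40.7) and at 34.6% of those with it (30.7 to 38.7; Fisher exact test, adjusted p = 0.863), while GAGACG was more frequent without it (26.1% against 15.5%, adjusted p = 0.00392). The 6-base sequences compared in this way were 3 and were chosen after the data were seen.

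Ribosomal protein genes were the gene group with the clearest excess of promoter peaks. Of 78 such genes, 12 (15.4%, interval 8.21 to 25.3) had an IDR peak in the promoter window, against 1.89% of all other coding genes (Fisher exact test, odds ratio 9.44, adjusted p = 6.34e-07). The strongest were at *rpl-20* (signal 63.2, IV 4749906 to 4750245, 298 bases upstream), *rpl-3* (50.2, III 3867438 to 3867777), *rpl-35* (49.7, III 7854505 to 7854844) and *rpl-15* (47, IV 654785 to 655124). All 12 peaks lay outside protein-coding genes, 84 to 532 bases from the start, 9 of them were also in the promoter window of another gene, and 3 held WGATAR. The odds ratio was 8.62 with the strongest regions of replicate 2 and 4.33 with those of replicate 1. With each peak assigned to the nearest start within 5000 bases, the *rpl-20* peak went to another gene. The odds ratio was then 3.49 (8 of 78). Restricted to IDR peaks with WGATAR, it was 2.95 (Fisher exact test, adjusted p = 0.210, range over 10 alternatives 2.30e-08 to 0.210).

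Among epidermal gene groups, 2 had more promoter peaks than other genes. Of 20 cuticle collagens named for body shape, 3 were bound (15%, odds ratio 8.97, adjusted p = 0.0405, Fisher exact test). They were *lon-3* (signal 39.3, 720 bases upstream), *dpy-10* (31.7, 424 bases upstream) and *dpy-2* (30.6, 349 bases upstream), all with WGATAR. The peaks of *dpy-10* (II 6712481 to 6712820) and *dpy-2* (II 6713773 to 6714112) lie close together, and the Fisher test counted these genes as independent. The summits at *lon-3* and *dpy-10* lay in introns of other coding genes. Of 22 epidermal antimicrobial peptide genes, 3 were bound (13.6%, odds ratio 8.02, adjusted exact p = 0.0405): *nlp-33* (46.6, no WGATAR), and *nlp-31* and *nlp-34*, whose starts share a single peak (44.8) with 4 WGATAR sequences. Neither call held with circular shifts in place of the Fisher test on the promoter window (adjusted p = 0.183 for both, ranges over 11 alternatives 0.00951 to 1 and 0.00296 to 1). The strongest 774 regions of replicate 2 reached 0 of these collagen genes, although all 3 peaks contained weaker replicate 2 summits (signal 11.9 at *lon-3*, 11.3 at *dpy-2* and 5.20 at *dpy-10*). The *dpy-10* value lay below the median of that list, 5.91, and the list holds background as well as peaks.

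The other epidermal groups did not pass with the IDR list, though several well-known genes had a peak. Of 15 epidermal transcription factors, *elt-3* and *nhr-23*, a nuclear hormone receptor needed for molting, were bound (adjusted exact p = 0.127). The *nhr-23* peak, at I 7216563 to 7216902, lay 51 bases upstream of a start and had a signal of 51.3. With the 387 strongest IDR peaks this list passed, with the same 2 genes (odds ratio 16.4, adjusted exact p = 0.0406, range over 14 alternatives 0.0264 to 1). That call depended on *elt-3*, where transgene copies can add reads, since without this gene 1 of 14 was bound (adjusted exact p = 0.469). Of 156 numbered collagens, 5 were bound (adjusted exact p = 0.444), led by *col-91* (57.1), *col-149* (38.3), *col-93* (36.7) and *col-42* (33.1). Single members were bound among molting and cuticle processing genes (*sym-1*, 1 of 28, adjusted exact p = 0.670), epidermal junction and cytoskeleton genes (*ifb-1*, an intermediate filament gene, 1 of 22, 0.606), and osmotic stress genes (*osm-11*, 1 of 11, 0.410). Patched-related genes had 2 of 26 (*ptr-13* and *ptr-15*, 0.254) and hedgehog-related genes 0 of 59, which allows a share of up to 5.08% by 3 counts of the total and 6.06% by the exact interval. Of 185 detoxification genes 6 were bound (adjusted exact p = 0.410), led by *gst-42* (52), *cyp-29A4* (43), *ugt-25* (38.1) and *ugt-26* (36.5), and all 6 peaks held WGATAR.

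Tyrosine catabolism genes differed between the replicates in whether they passed. With the IDR list *fah-1* alone was bound (1 of 5, adjusted exact p = 0.254), and likewise with the strongest regions of replicate 1 (1 of 5, 0.210). With the strongest regions of replicate 2, *fah-1*, *hgo-1* and *tatn-1* were bound (3 of 5, odds ratio 77.3, adjusted exact p = 6.46e-04), the latter pair named after their values were seen. The window from 2000 bases upstream gave 2 of 5 (adjusted exact p = 0.0476, range over 11 alternatives 6.46e-04 to 1). The difference between the replicates was not tested for this list.

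Nuclear hormone receptor genes had more promoter peaks than other genes, with 12 of 269 bound (4.46% against 1.91%, odds ratio 2.40, Fisher exact test, adjusted p = 0.0405). The strongest were at *nhr-80* (87), *nhr-23* (51.3), *nhr-34* (47) and *nhr-119* (44.4), and 13 of the 15 peaks in windows of this group held WGATAR. With the permutation by circular shifts the call was lost (adjusted p = 0.183), as it was with replicate 2 alone (0.414, range over 11 alternatives 0.00702 to 1).

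Marker genes of other tissues had no promoter peak in the IDR list. The counts were 0 of 33 intestinal genes, 0 of 26 body wall muscle genes, 0 of 18 pharyngeal genes, 0 of 34 neuronal genes and 0 of 29 germline genes. Lists of these sizes allow shares of up to 9.09%, 11.5%, 16.7%, 8.82% and 10.3% by 3 counts of the total, and of 10.6%, 13.2%, 18.5%, 10.3% and 11.9% by the exact interval, all above the 1.94% of all coding genes, so absence cannot be told from the general rate. Of 72 histone genes 1 was bound (*his-37*, adjusted exact p = 1).

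**Figure D3:**
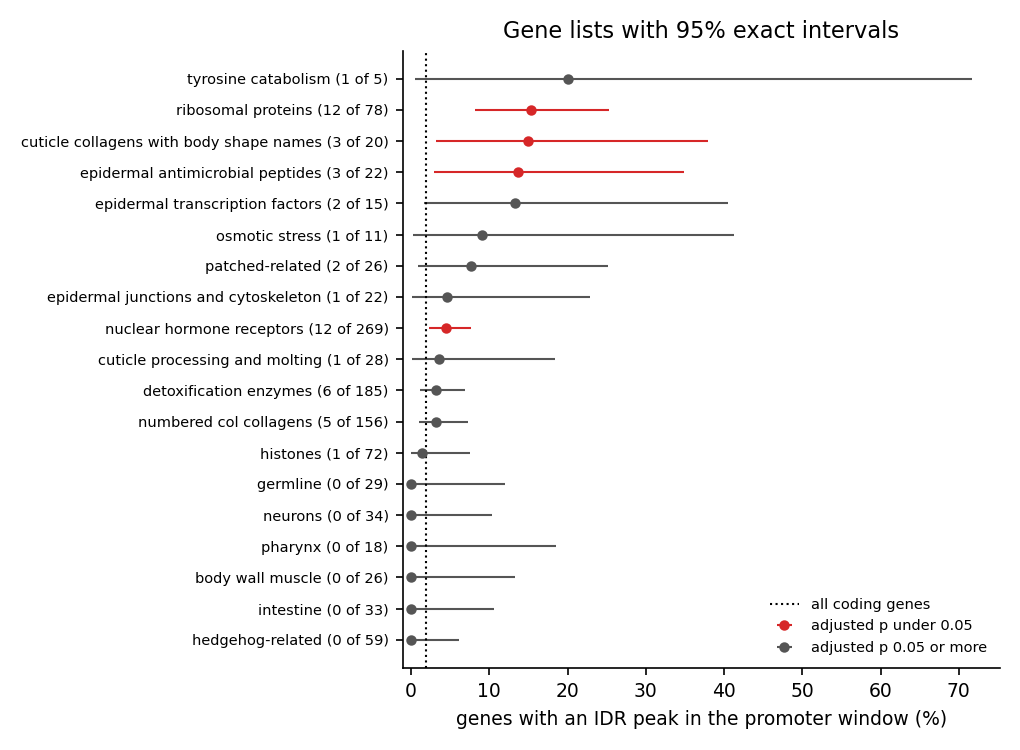
For each of 19 gene lists, the point is the share of members with an IDR peak in the promoter window (x axis, percent) and the line its 95% exact interval. Lists in red had an adjusted p under 0.05, and the dotted line is the share of all coding genes, 1.94%.

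Assigning each peak to the nearest coding start within 5000 bases raised the number of bound genes from 388 to 639 and the number of lists that passed the Fisher test from 4 to 8. With circular shifts in its place, a test added after the data were seen, 2 of the 8 passed, ribosomal protein genes (adjusted permutation p = 0.00380) and body-shape collagens (0.0247), so the other 6 calls rest on the Fisher test alone. Epidermal junction and cytoskeleton genes then had 5 of 22 members (22.7%, odds ratio 8.96, adjusted Fisher exact p = 0.0105, permutation by shifts 0.140). They included *mua-3* (65.6) and *mup-4* (58), which encode transmembrane proteins that anchor the epidermis, both with intronic peaks. Osmotic stress genes had 3 of 11 (adjusted exact p = 0.0211, by shifts 0.0814), patched-related genes 4 of 26 (0.0260, by shifts 0.205), tyrosine catabolism genes 2 of 5 (0.0260, by shifts 0.0646) and body-shape collagens 4 of 20 (0.0211, with *rol-6* and *rol-8*). Epidermal transcription factors had 3 of 15 (*elt-3*, *nhr-23* and *blmp-1*, adjusted exact p = 0.0264, by shifts 0.227), a call that again depended on *elt-3* and its possible transgene reads, since 2 of 14 were bound without it (adjusted exact p = 0.152). Ribosomal protein genes (8 of 78, 0.0211) and nuclear hormone receptors (17 of 269, adjusted exact p = 0.0260, by shifts 0.0519) passed the Fisher test as well, and antimicrobial peptide genes did not (3 of 22, 0.0674). Markers of other tissues had 1 of 26 in body wall muscle (*unc-52*), 1 of 34 in neurons (*mec-7*) and 1 of 29 in the germline (*glh-4*), or 3.85%, 2.94% and 3.45%, beside 3.20% of other genes in each case. Intestinal and pharyngeal genes had 0 of 33 and 0 of 18. The examples here were chosen after their values were seen.

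Peaks were denser on the X chromosome than on the autosomes. X held 180 IDR peaks, 10.2 per Mb, against 7.20 per Mb on the autosomes (ratio 1.41, exact binomial test, p = 8.81e-05). Autosomal densities ranged from 5.40 per Mb on V to 9.22 per Mb on I. Pooled regions below the IDR threshold had a ratio of 1.15. With their X share as reference the odds ratio against the combined autosomes was 1.22 (Fisher exact test, p = 0.0226). On that reference III (117 IDR peaks, 3892 other regions) was close to X (180 and 5802).

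Peaks with WGATAR were slightly stronger. Their median signal was 37.9, against 35.0 without it, a difference of 0.12 on the log2 scale (permutation test, p = 2.2e-04). Among the 205 peaks with at least 3 WGATAR sequences the median was 41.2. In the same permutation test the difference fell short of the threshold among the 387 strongest peaks (0.06, p = 0.108) and in replicate 2 alone (0.03, p = 0.292).

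The *elt-3* locus held many called regions, most of them below the IDR threshold. Within 20 kb of the gene midpoint (gene at X 13934874 to 13941216, plus strand) lay 29 pooled regions, against a median of 13 in 440 other X windows of that size, of which 1 held as many (one-sided p = 0.00454 from the exact rank). Of them 23 were below the IDR threshold, in a list that holds background as well as peaks, and 6 were IDR peaks, more than the 4 of any other X window. The strongest pair were intronic, at X 13937315 to 13937654 (signal 92.5, 5 WGATAR sequences) and X 13937999 to 13938338 (80.4, 574 bases upstream of an internal start). Another intronic peak lay at X 13939368 to 13939707 (36.3) and one downstream of the gene at X 13941289 to 13941628 (53.5). Others were in the 5′ UTR of *alg-1*, an Argonaute gene (33.8, X 13949313 to 13949652), and at X 13919952 to 13920291 (31.8). The count was 35 in replicate 1 and 29 in replicate 2. The strain carries extra *elt-3* sequence in its transgene, and reads from it would map to this position. Whether the lists were corrected with a control of the same strain is not given in the sources used here. At *unc-119* (III 10902641 to 10908935), 11 pooled regions lay within 20 kb, against a median of 12 on that chromosome, and none was an IDR peak.

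**Figure D4:**
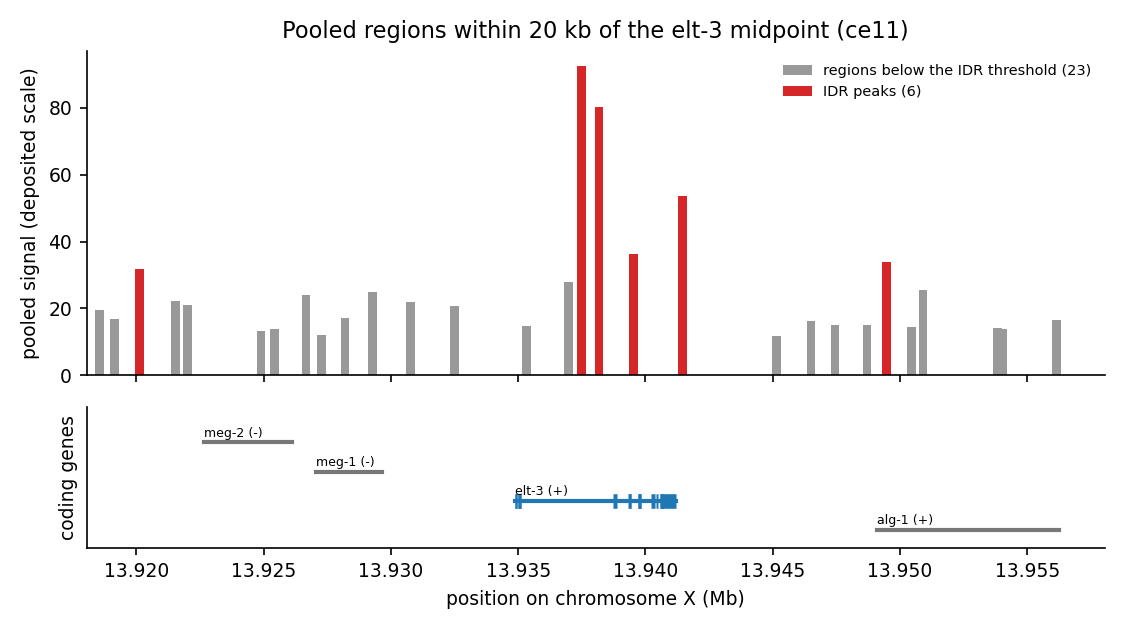
The upper panel shows pooled regions within 20 kb of the elt-3 midpoint as bars at their position on X (x axis, Mb, ce11) with the pooled signal on the deposited scale (y axis), IDR peaks in red and other regions in grey. The lower panel shows protein-coding genes with strand, with thick elt-3 exons. The tallest bars, 92.5 and 80.4, stand in the elt-3 introns.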

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

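Alternatives with peaks split by WGATAR or by promoter window, epidermal factors without elt-3, other gene types, other control genes, pooled regions as control for 6-base sequences and X, and shifts with the nearest start were chosen after seeing the data. Replicate overlap (40.1 to 44.8%), promoter share (32.3 to 59.3%), WGATAR share (56.5 to 81.1%) and the X excess (ratio 1.32 to 1.52, odds ratio 1.22 against other regions) kept their direction and side of the threshold under each alternative run for them. Enriched 6-base sequences numbered 288 with the 387 strongest peaks, where fewer windows were tested. The number of gene lists that passed, 4 in the report, was 2 to 4 without 1 replicate, 2 with the window from 500 bases upstream, 8 with the nearest start, 2 with the nearest start and circular shifts, 1 with circular shifts alone, 2 with only WGATAR peaks and 1 with only peaks lacking it, and the cause was not tested. Of the 4 lists, 1 passed with replicate 2 alone, beside tyrosine catabolism (odds ratio 77.3), and all 4 with replicate 1 alone; 3 passed with the nearest start, beside 5 others. The difference in strength was 0.0647 with the 387 strongest peaks and 0.0341 to 0.112 without 1 replicate, as log2 values. The elt-3 locus held 13 regions within 10 kb (exact rank p = 0.0498) and 49 within 50 kb (exact rank p = 0.0568). The wider window takes in more flanking sequence. Odds ratios changed side for lists with few bound genes. Without 1 replicate they ran from 0 to 12.9 for body-shape collagens, 0 to 4.29 for patched-related, 0 to 5.13 for osmotic stress, 0 to 5.15 for epidermal junction, 0 to 1.80 for hedgehog-related, 0 to 2.05 for body wall muscle and 0 to 1.56 for neuronal genes. They were 0 with the 387 strongest peaks for patched-related, osmotic stress and epidermal junction genes. With only peaks lacking WGATAR they were 0 for these 3 lists and for body-shape collagens, epidermal transcription factors, tyrosine catabolism, detoxification and molting genes. Lists with less than the general share rose above it for histones (1.48 with the 387 strongest peaks, 1.01 from 500 bases upstream, 1.03 with only WGATAR peaks), intestine (1.08 from 2000 bases upstream), germline (1.23 from 2000 bases upstream, 1.08 with the nearest start) and body wall muscle (1.21 with the nearest start). The counts behind these are small, and none of these changes of side passed the test. Leaving out 1 replicate keeps a single list, so no spread between replicates can be had. Of 37 named genes with a peak, 28 kept one among the 774 strongest regions of replicate 2 and 34 among those of replicate 1. This is a cutoff on rank. In the whole lists, which hold background as well, 774 IDR peaks overlapped a region of replicate 1 and 767 a region of replicate 2. Depth is unknown, so a site absent from a list cannot be told from one sequenced too thinly.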

Other observations

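IDR peaks also lay near short noncoding genes. The tests of X shares against other regions and against the share of WGATAR sites, and on the region-rich part of X, were chosen after the result was seen, as were the counts at noncoding genes. IDR summits fell within 200 bases of a tRNA gene 13 times (1.68% against 0.305% after circular shifts), of a snoRNA gene 9 times (1.16% against 0.184%; both p = 2e-04, the smallest possible) and of a snRNA gene 5 times (0.646% against 0.0585%, permutation p = 4e-04). Long intergenic RNA genes had 8 (1.03% against 0.321%, adjusted permutation p = 0.0139), microRNA genes 3 (0.388% against 0.124%, p = 0.160), and pseudogenes 2 (0.258% against 3.65%, adjusted p = 4e-04). The peaks at tRNA, snoRNA and snRNA genes held WGATAR in 6 of 27 cases (22.2%, interval 8.62 to 42.3), against 76.2% of other peaks (Fisher exact test, p = 1.15e-08), and none of the 5 at snRNA genes held it. The flanking windows of all IDR peaks held it in 38.8%, so background of the assay stays open for these peaks.

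Ribosomal protein promoters held more peaks than other genes, yet 3 of their 12 peaks (25%, interval 5.49 to 57.2) held WGATAR against 75.1% of other peaks (Fisher exact test, p = 4.42e-04). That low share is consistent with signal at active promoters that does not come from the GATA sequence, through other proteins or as background of the assay. The strongest regions of replicate 2 argue against replicate 1 alone as its source (odds ratio 8.62). A control without the tagged factor was not analysed here, so direct binding at weaker sequences, recruitment and background stay open, and no biological explanation was tested.

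The excess of X over the combined autosomes remained with other pooled regions as reference (odds ratio 1.22). It also remained without the peaks within 50 kb of elt-3 (ratio 1.35, exact binomial test, p = 7.55e-04). For the combined autosomes, this argues against both a general excess of called regions and the elt-3 locus as the whole of it. Relative to other regions, however, X (180 IDR peaks, 5802 other regions) was close to III (117 and 3892), and V (113 and 5654) was lowest. The tests ignored this spread between autosomes, so on that reference X was not set apart from each autosome. WGATAR sites were 1.1004 times as dense on X as on the autosomes, between the bounds of 1.1 and 1.2 set for that ratio before it was computed, so the ratio decided nothing. For peaks with WGATAR, the X share of 21.2% (interval 17.9 to 24.8) took in the 19.1% of all WGATAR sites that lie on X (exact binomial test, p = 0.203), so site density may account for that part. Peaks without WGATAR had an X share of 29.1% (22.9 to 36), above the 19.9% of other regions (Fisher exact test, p = 0.00174), which site density leaves unexplained. The reference for these peaks was other regions, with and without WGATAR, and not WGATAR sites. Set directly against the peaks with WGATAR, their odds ratio for lying on X was 1.53. No biological explanation was tested.

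Regions crowded around elt-3 within 10 kb (13) and from 10 to 20 kb (16) of its midpoint. For the part within 10 kb, the median of 883 other X windows of that size was 6, and 43 held as many (one-sided p = 0.0498 from the exact rank). From 20 to 60 kb there were 29, against a median of 27 and a 95th percentile of 39 on X, which argues against a generally region-rich part of the chromosome. Extra template from the transgene could add weak regions without the GATA sequence: those below the IDR threshold within 20 kb held WGATAR in 11 of 23 cases (47.8%, interval 26.8 to 69.4), against 40.3% of all such regions. Transgene copies and binding of ELT-3 at its own gene cannot be told apart with so few regions, and a control of the same strain, if one was used, would already remove part of the first.

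A further hypothesis was that peaks without WGATAR near the summit have it just outside. Of 199 such peaks, 95 (47.7%, interval 40.6 to 54.9) held it more than 100 and up to 200 bases away, against 36.7% of the same intervals around points 700 bases away (Fisher exact test, p = 0.0104), so a displaced site may account for some of them. The pairing of these points with their peaks was not used in the test.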
